A study of Mus musculus with 9 samples.

How the data were processed

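RNA sequencing was applied to mouse hepatocytes that had been turned into liver progenitor cells, transduced with a lentivirus, matured again into hepatocytes for 3 weeks and exposed to copper chloride for 24 hours. The labels' protocols give a copper dose of 100 µM, and the treatment field of the same labels gives the same figure in mM. The series has 9 samples in 3 groups of 3: Atp7b knockout cells with an ATP7B lentivirus (KO-ATP7B), knockout cells with a GFP lentivirus (KO-GFP) and wild-type cells with a GFP lentivirus (WT-GFP). The growth protocol names the wild-type cells as carrying ATP7B, whereas the titles and the design text name GFP, and the titles' name is used here. Libraries were made with a stranded mRNA kit, per the labels' protocols.

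The authors deposited raw read counts per gene symbol in a table of 9 count columns, which are numbered and carry no group name. Only 2 of these columns could be tied to a sample, because those 2 samples also have files of their own with the same number in the name and the header. They are WT-GFP replicates 1 and 2. The other 7 count columns were not used here, since no label used here says which sample each one is, and neither column order nor values were taken in place of a label. The 3 comparisons planned before the data were examined (KO-GFP with WT-GFP, KO-ATP7B with KO-GFP, KO-ATP7B with WT-GFP) were kept as written but could not be run, and nor could their edgeR quasi-likelihood tests, gene list tests and count of opposed calls. What is given instead is the expression profile of the WT-GFP cells in 2 libraries and the spread between them. There is no comparison between genotypes or vectors and no background from cells without copper. Only the gene lists and 5 fixed genes were chosen before the data were examined, and all other tests, settings and alternatives were chosen afterwards.

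The authors deposited FPKM values for the same 2 libraries, per the file headers. The submitters' processing notes name HISAT2 2.2.1.0 and the builds mm10 and hg38, without a role for either build. The read counter, the annotation, the strand setting and the tool behind the FPKM are not given in the sources used here. Gene lengths implied by the counts and FPKM, with the column total as library size, were whole numbers of bases within 0.01 bp for 100% of the 15545 genes with a count. The deposited FPKM are therefore the same counts divided by library total and gene length, and not a second measurement. They hold no correction for RNA composition. Of the 21878 symbols in the table, 20624 were found in GENCODE release M21 on GRCm38, the assembly of mm10, from which gene positions, exon lengths and GC content were taken.

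Total counts were 18532457 in replicate 1 and 17821682 in replicate 2. A count of 0 allows up to 3 counts, which is 0.162 CPM in replicate 1 and 0.168 CPM in replicate 2. Intervals are 95% binomial, Wilson for the joint share of several genes and exact Clopper-Pearson for single genes. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules. Levels of genes are means of the deposited FPKM ± SD over the 2 libraries. A list's median is taken over its members' means, with the medians in replicates 1 and 2 beside it for some lists. No label says whether the replicates came from separate mice or cultures, so p-values measure only differences between these libraries, which may be technical.

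Of the 27 gene lists, 26 had members in the table. The list of mitochondrially encoded genes, and symbols of other lists missing from the table, were not analysed here. Some genes stand in more than 1 list, among them the ferritins, Trf and Sqstm1. Members were counted at 10 FPKM or more and below 1 FPKM, and the median of the members' FPKM ranks was set beside the medians of 10000 random lists of the same size drawn from all symbols. Of these 21878 symbols only 15545 had a count, so a list of expressed genes tends to rank high. The percentages therefore do not set a list apart from other expressed genes. The mature hepatocyte and the progenitor and biliary lists were compared by their median log2(FPKM + 1) in a two-sided permutation test over genes with 100000 permutations. Genes are not independent replicates, so these values describe the 2 libraries.

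Counts of replicate 2 were compared with those of replicate 1 by a two-sided exact binomial test per gene, given the library totals, over the 12302 genes with a mean of at least 10 counts, with Benjamini-Hochberg adjustment at 0.05. The test compares 2 libraries of 1 group, not conditions. A first pass had no filter, and the minimum of 10 counts was chosen after its number of differing genes had been seen. Log2 ratios are of replicate 2 to replicate 1 with 0.5 added to each count. List medians of these ratios were set beside 10000 random lists matched on mean count in 20 bins. TMM factors and a common dispersion came from edgeR 4.0.16. On counts simulated for this comparison, with 12302 genes of which 200 were changed, the binomial test recovered 54.5% of 1.25-fold changes with 4 false calls and 89.0% of 2.0-fold changes with 9 false calls. The simulated counts held counting error only. Few false calls are then built in, and they do not give the error rate for real libraries, which vary by more than that. Of 100 simulated lists shifted by 0.2, 100 lay outside the middle 95% of random lists, as did 4 of 100 lists without a shift. The simulated lists were all of the same size, with genes that varied independently and equally at every expression level. These figures therefore do not carry over to short lists, to genes with few counts or to genes that vary together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and R 4.3.3 were used.

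The planned rule for naming genes relied on the comparisons that were not run, apart from the fixed genes Atp7b, Mt1, Mt2, Slc31a1 and Alb. In its place, a rule was set once the usable columns were known and before the level of any listed gene was looked at. It names the fixed genes, the 10 genes with the largest share of counts, the 3 members of each list with the highest FPKM, and the 5 genes each way with the largest ratio between the libraries among those past the test at a mean of at least 5 CPM, skipping symbols of unnamed gene models. Some genes that the rule names are not reported here. Genes named outside this rule are said to be chosen after their values were seen. Alternatives tried were TMM scaling, GENCODE exon lengths, other minimum counts and pseudocounts, a minimum ratio, each library alone, and removal of lowess trends (span 0.3) on GC content and gene length.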

Results

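The data are the transcriptomes of 2 libraries of WT-GFP cells, replicates 1 and 2 of a group of 3. These cells were hepatocytes of wild-type C57BL/6 mice that had been reprogrammed to liver progenitors, transduced with GFP, matured again and exposed to copper for 24 hours. In the study they are the reference for cells lacking Atp7b, the copper-exporting ATPase that is defective in Wilson disease. Replicate 1 held 18532457 counts over 14759 genes and replicate 2 held 17821682 counts over 14923 genes. A level of at least 1 FPKM was reached by 10680 genes in each library. The 10 most abundant genes took 4.83% of the counts in replicate 1 (95% Wilson interval 4.82 to 4.84%) and 4.56% in replicate 2 (4.55 to 4.57%).

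The largest shares of counts were those of Fth1, Eef1a1, Ahnak and Clu. Fth1, the ferritin heavy chain, held 0.728% ± 0.0316 of the counts (SD, n = 2) and Ftl1, the ferritin light chain, 0.425% ± 0.0047. The translation elongation factors Eef1a1 and Eef2 held 0.723% ± 0.0259 and 0.310% ± 0.000868. Clu, the secreted chaperone clusterin, held 0.530% ± 0.0672, and Ahnak, a very large scaffold protein, 0.570% ± 0.00932. Aldh1a1, a retinaldehyde dehydrogenase, held 0.375% ± 0.000728, and Fn1 (fibronectin) 0.357% ± 0.0121. The fatty acid desaturase gene Scd2 held 0.356% ± 0.045. Ferritin and Eef1a1 genes have many processed pseudogenes, and their levels are uncertain because the treatment of shared reads is not given in the sources used here.

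Mt1 and Mt2, which encode metallothioneins, small cysteine-rich proteins that bind copper and zinc, stood among the most highly expressed genes of the copper-exposed cells. Mt2 (ENSMUSG00000031762.7, chromosome 8, 94172664 to 94173568, plus strand, GRCm38) was at 3211 ± 119 FPKM (SD, n = 2), rank 5 of all symbols, and Mt1 (ENSMUSG00000031765.8, chromosome 8, 94179082 to 94180327, plus strand) at 2055 ± 60.5 FPKM, rank 7. Together they took 0.335% ± 0.0112 of all counts. The metallothionein genes Mt3 and Mt4, chosen after their values were seen, were at 4.56 ± 0.488 FPKM and 2.61 ± 0.371 FPKM. The zinc exporter gene Slc30a1 was at 21.8 ± 0.921 FPKM. Mt1, Mt2 and Slc30a1 were the 3 of 8 members of the metallothionein and zinc/copper response list that reached 10 FPKM, and the list median of 4.61 FPKM ranked above 77.3% of random lists. With GENCODE exon lengths Mt1 came to 1253 FPKM. Cells without copper were not analysed here, so no change on copper exposure is given.

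Genes of copper import, delivery and export were expressed. Atp7b itself (ENSMUSG00000006567.11, chromosome 8, 21992785 to 22060305, minus strand, protein-coding) was at 7.06 ± 0.911 FPKM (SD, n = 2), from 979 and 784 counts in replicates 1 and 2. These correspond to 52.8 CPM (95% exact interval 49.6 to 56.2) and 44.0 CPM (41.0 to 47.2). Atp7b thus differed between the libraries by more than counting error (log2 ratio -0.26, adjusted p = 0.00226, exact binomial test). The same test called 1816 of 12302 genes (14.8%), so passing it is not particular to Atp7b. Slc31a1, the main copper importer (ENSMUSG00000066150.12, chromosome 4, 62360727 to 62391769, plus strand, protein-coding), was at 33.8 ± 0.543 FPKM, and no difference between the libraries was detected (log2 ratio 0.03, adjusted p = 0.698, exact binomial test). Among copper handling genes chosen after their values were seen, the copper ATPase gene Atp7a was at 11.4 ± 0.718 FPKM, above Atp7b. The copper chaperone genes Atox1 and Ccs were at 189 ± 1.61 FPKM and 48.7 ± 0.584 FPKM. Of the 21 copper handling genes 12 reached 10 FPKM and 5 were below 1 FPKM. The highest were Sod1, the copper/zinc superoxide dismutase, at 488 ± 16.3 FPKM, Cp, the secreted copper protein ceruloplasmin, at 284 ± 8.99 FPKM, and Slc25a3, a mitochondrial phosphate and copper carrier, at 272 ± 5.69 FPKM. The list median was 16.0 FPKM (16.8 and 15.2 FPKM by library), above 99.9% of random lists, which include genes with no counts.

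Genes of the oxidative, proteotoxic and endoplasmic reticulum stress responses were expressed at high levels as groups. Of 28 NRF2 target genes 25 reached 10 FPKM, and their median of 137 FPKM (133 and 142 FPKM by library) was the highest of the 26 lists. Fth1 (7726 ± 335 FPKM), Ftl1 (4386 ± 48.5 FPKM) and the peroxidase gene Prdx1 (1271 ± 29.5 FPKM) led this list. Among members chosen after their values were seen, the heme-degrading enzyme gene Hmox1 was at 562 ± 51.4 FPKM and the quinone reductase gene Nqo1 at 1.36 ± 0.739 FPKM. All 20 heat shock genes reached 10 FPKM, with a median of 91.1 FPKM (86.9 and 108 FPKM by library), led by the chaperones Hspa8 (1139 ± 112 FPKM), Hsp90ab1 (938 ± 31.4 FPKM) and Hsp90aa1 (699 ± 88.6 FPKM). All 24 genes of the unfolded protein and integrated stress response did so too, with a median of 66.2 FPKM (67.5 and 64.9 FPKM by library). Calr, a chaperone of the endoplasmic reticulum, was at 528 ± 53.5 FPKM, Psat1, an enzyme of serine synthesis, at 519 ± 17.7 FPKM, and Hspa5 (BiP) at 419.8 ± 10.2 FPKM. The median ranks of these 3 lists lay above 100% of random lists, which include genes with no counts, as did those of cholesterol synthesis, fatty acid oxidation, p53 target, oxidative phosphorylation, iron handling and lysosome genes. With GENCODE exon lengths Fth1 came to 4671 FPKM and Prdx1 to 708 FPKM. The heat shock and unfolded protein medians were below that of oxidative phosphorylation genes (99.3 FPKM). Without cells that had no copper, these levels do not show that a stress response was active.

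**Figure D1:**
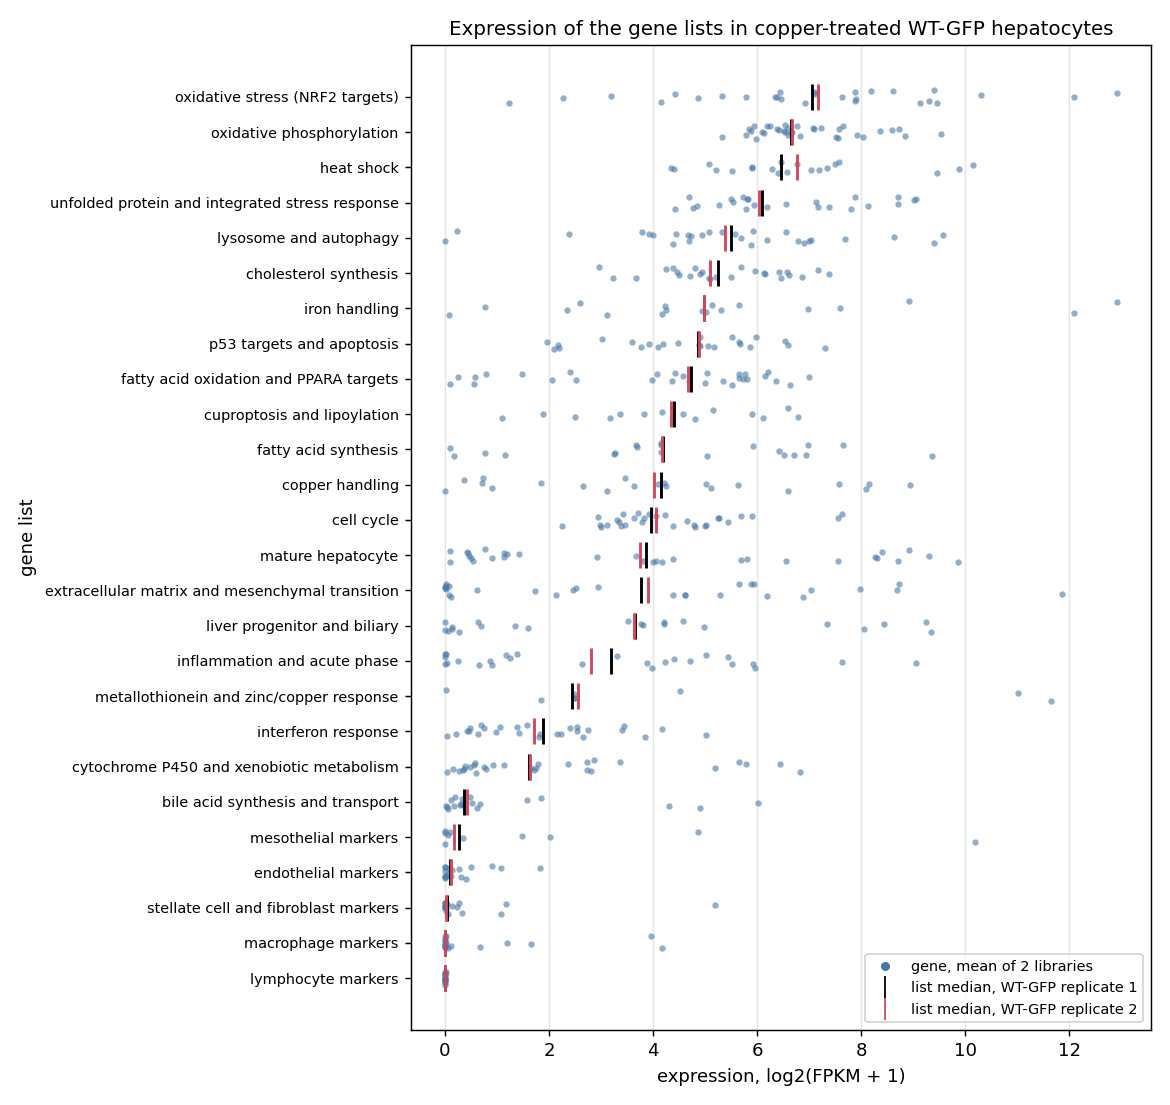
Expression of 26 gene lists on a log2(FPKM + 1) axis. Points are single genes (mean of 2 WT-GFP libraries), and black and red ticks are the list medians in replicates 1 and 2, which run from 133 and 142 FPKM for NRF2 targets to 0 for macrophage and lymphocyte markers.

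Hepatocyte genes and progenitor or biliary genes were expressed side by side. Albumin (Alb, ENSMUSG00000029368.10, chromosome 5, 90460897 to 90476602, plus strand, protein-coding) was at 929.6 ± 33.4 FPKM, the fibrinogen chain gene Fgb at 633 ± 50.9 FPKM and the transferrin gene Trf at 482 ± 43.6 FPKM. Of 31 mature hepatocyte genes 17 reached 10 FPKM and 9 were below 1 FPKM. Their median of 13.0 FPKM (13.5 and 12.5 FPKM by library) ranked above 99.98% of random lists, which include genes with no counts. Further members were chosen after their values were seen. The hepatocyte transcription factor gene Hnf4a was at 50.4 ± 0.351 FPKM. Of the urea cycle genes, Cps1 was at 1.21 FPKM, Ass1 at 1.28 FPKM, Arg1 at 0.370 FPKM and Otc at 0.0721 FPKM. Of the gluconeogenic genes, Pck1 was at 0.337 FPKM and G6pc at 0.452 FPKM. Of 22 progenitor and biliary genes 12 reached 10 FPKM and 8 were below 1 FPKM. Their median of 11.5 FPKM (11.6 and 11.4 FPKM by library) ranked above 99.6% of such random lists. The surface glycoprotein gene Cd24a was at 649 ± 27.0 FPKM, Spp1 (osteopontin) at 604 ± 27.9 FPKM and the biliary keratin gene Krt19 at 344 ± 36.5 FPKM. Median log2(FPKM + 1) was 3.81 for the hepatocyte and 3.64 for the progenitor and biliary list, a difference of 0.17 that was not detected as different from 0 (p = 0.818, two-sided permutation test over 31 and 22 genes). With GENCODE exon lengths, which put the progenitor and biliary median at 4.91 FPKM and Fgb at 283 FPKM, the difference was 1.26 (p = 0.521, same permutation test). Over members with at least 10 counts, which put that median at 17.5 FPKM, it was -0.18. The test shuffles genes of widely different levels between the lists and did not detect even a difference of 1.26. Its outcome therefore does not show that the lists were expressed equally.

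Most bile acid genes were below 1 FPKM, and few genes of drug metabolism reached 10 FPKM. Of 19 bile acid genes 14 were below 1 FPKM, and the median of 0.271 FPKM (0.567 FPKM over members with at least 10 counts) ranked above 35.2% of random lists. The efflux pump genes Abcc3 (64.0 ± 2.76 FPKM) and Abcc2 (18.7 ± 1.3 FPKM) and the bile acid receptor gene Nr1h4 (28.7 ± 0.169 FPKM) were the members at 10 FPKM or more. Cyp7a1, the rate-limiting enzyme of bile acid synthesis and chosen after its value was seen, had 10 and 6 counts. Of 29 cytochrome P450 and xenobiotic genes 5 reached 10 FPKM and 13 were below 1 FPKM (median 2.15 FPKM, above 71.5% of random lists). Cyp3a13 was at 113 ± 3.51 FPKM, Cyp3a11 at 85.9 ± 17.7 FPKM and the carboxylesterase gene Ces2a at 54.3 ± 12.9 FPKM.

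Lipid and energy metabolism genes were broadly expressed. All 35 nuclear genes of oxidative phosphorylation in the table reached 10 FPKM (median 99.3 FPKM, 98.9 and 101 FPKM by library), with Atp5b at 741 ± 13.6 FPKM, Cox4i1 at 459 ± 23.0 FPKM and Cox6a1 at 424 ± 24.0 FPKM. Cholesterol synthesis genes did so in 24 of 26 cases (median 34.6 FPKM, 37.1 and 33.0 FPKM by library), led by Fdps (165 ± 22.8 FPKM) and Msmo1 (142 ± 12.4 FPKM). Fatty acid synthesis genes did so in 14 of 20 cases, led by the desaturase genes Scd2 (653 ± 82.6 FPKM) and Fads2 (199 ± 14.1 FPKM, or 95.3 FPKM with GENCODE exon lengths) and by Me1 (125 ± 3.7 FPKM). Fatty acid oxidation and PPARA target genes did so in 20 of 29 cases, among them Acadl (98.7 ± 3.18 FPKM) and Ech1 (81.1 ± 0.287 FPKM). In the cuproptosis list, which holds lipoylated mitochondrial enzymes and the proteins that modify them, 9 of 14 genes reached 10 FPKM. Its highest members were the pyruvate dehydrogenase genes Pdha1 (109 ± 2.51 FPKM) and Pdhb (96.2 ± 2.14 FPKM) and Dlst (68.2 ± 1.55 FPKM). Iron handling genes reached 10 FPKM in 13 of 18 cases (median 30.6 FPKM), with the ferritins and Trf highest. Lysosome and autophagy genes did so in 25 of 28 cases, led by Ctsd (757 ± 19.3 FPKM), Sqstm1 (671 ± 84.9 FPKM) and Lamp1 (398 ± 19.6 FPKM).

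Transcripts of dividing cells and p53 targets were both present. Of 30 cell cycle genes 21 reached 10 FPKM and the other 9 lay between 1 and 10 FPKM. Pcna, the replication clamp, was at 198 ± 12 FPKM, Rrm2, a subunit of ribonucleotide reductase, at 187 ± 4.08 FPKM, and Mcm7, of the replicative helicase, at 58.5 ± 3.49 FPKM. Of 24 p53 target and apoptosis genes 19 reached 10 FPKM, with Cdkn1a (p21) at 158 ± 6.0 FPKM, Ccng1 at 95.6 ± 3.58 FPKM and Perp at 91.7 ± 0.35 FPKM. Inflammation and acute phase genes did so in 12 of 26 cases, led by the hemopexin gene Hpx (527 ± 6.71 FPKM), Lcn2 (197 ± 5.37 FPKM) and the chemokine gene Ccl2 (61.6 ± 7.76 FPKM). Their median was 7.07 FPKM (8.10 and 6.04 FPKM by library), or 3.72 FPKM with GENCODE exon lengths and 17.8 FPKM over members with at least 10 counts. Of 27 interferon response genes 3 did so, namely Bst2 (31.4 ± 1.07 FPKM), Stat2 (17.1 ± 0.943 FPKM) and Ddx58 (13.4 ± 0.581 FPKM).

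Most markers of endothelial cells, stellate cells, macrophages and lymphocytes were below 1 FPKM. Among 18 endothelial markers 16 were below 1 FPKM, and the highest were Egfl7 (2.53 ± 0.524 FPKM), Ptprb (1.11 ± 0.0728 FPKM) and Oit3 (0.882 ± 0.096 FPKM). Among 20 stellate cell and fibroblast markers 17 were below 1 FPKM. The highest were Ecm1 (35.4 ± 2.0 FPKM), Reln (1.10 ± 0.173 FPKM) and Pth1r (100 and 46 counts, and 0.810 FPKM in replicate 2 alone). Among 18 macrophage markers 14 were below 1 FPKM and 9 had no counts, while the lysosomal protein gene Cd68 was at 17.1 ± 3.34 FPKM, Cd14 at 14.5 ± 0.653 FPKM and Csf1r at 2.15 ± 0.249 FPKM. Of 14 lymphocyte markers 13 had no counts, which allows up to 0.162 and 0.168 CPM each, and Cd79a had 1 count in replicate 1. Among 10 mesothelial markers Msln (mesothelin) was at 1159 ± 20.7 FPKM, Upk1b at 28.1 ± 2.22 FPKM and Upk3b at 3.06 ± 0.393 FPKM (1.77 FPKM with GENCODE exon lengths), and 6 were below 1 FPKM. Among 28 matrix and mesenchymal transition genes 14 reached 10 FPKM and 9 were below 1 FPKM, led by S100a6 (3731 ± 47.2 FPKM), Fn1 (424 ± 14.3 FPKM) and the intermediate filament gene Vim (411 ± 21.3 FPKM). The median of this last list was 13.3 FPKM, or 7.37 FPKM with GENCODE exon lengths and 43.8 FPKM over members with at least 10 counts.

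Heat shock genes were higher in replicate 2 than in replicate 1 and cholesterol synthesis genes lower, the lists being singled out from 24 after their medians were seen. Of the 20 heat shock genes 16 were higher in replicate 2 and 0 lower (17 and 0 adjusted over the list alone), with a median log2 ratio of 0.20 against a middle 95% of -0.05 to 0.05 in random lists. The inducible Hsp70 genes Hspa1a (ENSMUSG00000091971.3, chromosome 17, 34969190 to 34972156, minus strand) and Hspa1b (ENSMUSG00000090877.3, chromosome 17, 34956436 to 34959238, minus strand) had 2478 and 5908 counts and 4680 and 10045 counts, log2 ratios of 1.31 and 1.16. They are near-identical copies, so how reads were split between them is uncertain. Of 26 cholesterol synthesis genes 20 were lower and 1 higher (21 and 1 adjusted over the list alone), with a median of -0.18 against -0.04 to 0.05. Mt1 and Mt2 were higher by log2 ratios of 0.06 and 0.08 (adjusted p = 2.52e-05 and 2.02e-09, exact binomial test), and Alb had a log2 ratio of -0.07 (adjusted p = 1.70e-09, exact binomial test). The ratios of Mt1, Mt2 and Alb were smaller in size than the SD of 0.11 over genes above 1000 counts. They passed the test because of their high counts and do not stand out from other abundant genes. The other genes with the largest ratios were P2rx7 (1.49), an ATP-gated channel gene, Nppb (1.30), which encodes a natriuretic peptide, and Rnaset2b (1.27) among the higher. Clca4b (-0.91), Pax8 (-0.86), Nhsl2 (-0.80), Nek3 (-0.80) and Serpina1d (-0.76) stood at the lower end. These lower genes and P2rx7 had low means, from 5.55 CPM for Pax8 to 7.41 CPM for P2rx7, near the minimum of 5 CPM. Rnaset2b and Serpina1d have near-identical copies and are uncertain.

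Over all genes the libraries were close but differed by more than sampling noise. Chi-square over genes was 5.25 times its 12301 degrees of freedom, so they were not treated as 1 library deposited in duplicate, though this does not show that they came from separate cultures. Across genes, which are not independent replicates, Pearson's r of log2 CPM was 0.994, and the coefficient of variation beyond counting error from edgeR was 5.59%. The SD of the log2 ratio was 0.57 for genes with a mean of 10 to 100 counts and 0.11 for the 4408 genes above 1000 counts. By the exact binomial test 1816 of 12302 genes (14.8%) differed, 1031 higher and 785 lower in replicate 2. With TMM scaling 836 were higher and 958 lower. Without TMM scaling, 188 genes differed by a log2 ratio of at least 0.5.

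**Figure D2:**
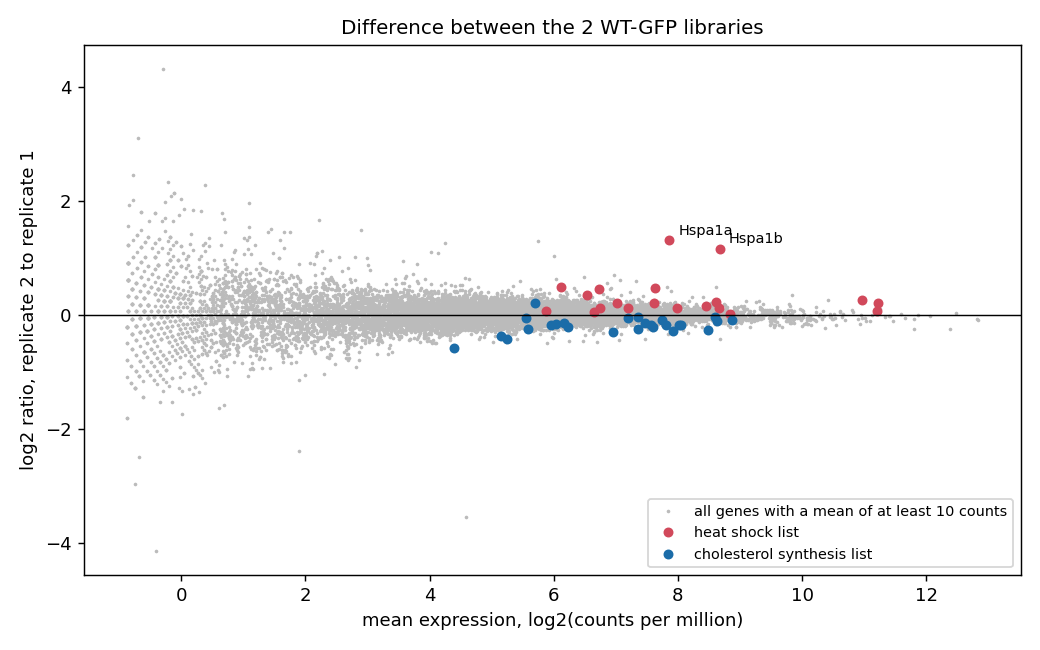
Log2 ratio of replicate 2 to replicate 1 against log2 mean CPM for genes with a mean of at least 10 counts (gray). Heat shock genes (red) have a median of 0.20, with Hspa1a at 1.31 and Hspa1b at 1.16, and cholesterol synthesis genes (blue) one of -0.18.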

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

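All alternatives here were chosen after the data were seen, since the planned ones belong to the 3 comparisons that could not be run: other scaling (RLE factors or none), DESeq2, limma-voom, other filters and fold thresholds, fits of fewer groups, camera with an estimated correlation, fry, the replicate number as a term, and leaving out each of 9 libraries were not run. No paired analysis was possible because only 2 libraries, both of the WT-GFP group, could be tied to a sample. Of 1816 genes differing between these, the number became 1794 with TMM scaling, 1680 without a filter, 1810 at a mean of at least 50 counts and 188 with a log2 ratio of at least 0.5, which by construction leaves out small differences. The hepatocyte minus progenitor and biliary difference passed the threshold under none of 5 alternatives, at 1.26 with GENCODE exon lengths, 0.18 with a pseudocount of 0.1, -0.18 over members with at least 10 counts, and 0.13 to 0.21 in single libraries. Median log2 ratios stayed outside random lists after removal of trends on GC content and gene length, at 0.16 and 0.19 for heat shock and -0.19 and -0.17 for cholesterol synthesis, and the heat shock median was 0.18 without Hspa1a and Hspa1b. TMM scaling moves a list and random lists by the same amount and a minimum of 50 counts removed no member, so neither tests these medians. GENCODE exon lengths moved the FPKM of 6 of 83 named genes and the medians of 3 of 26 lists by over 1.5 times, TMM scaling moved none that far, and members with at least 10 counts raised 8 of 25 list medians that far, by construction. In replicate 2 alone the stellate cell median was 0.00998 FPKM and Cd79a was at 0, as was the macrophage median in each library alone. Depth limits the marker lists of other cell types, whose medians rest on a few counts.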

Other observations

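Msln, whose level was singled out after it was seen, was among the more abundant transcripts while most other mesothelial markers were below 1 FPKM. Msln (ENSMUSG00000063011.7, chromosome 17, 25748613 to 25754378, minus strand, GRCm38) was at 1159 ± 20.7 FPKM, beside Alb at 929.6 ± 33.4 FPKM, whereas Wt1 was at 0.266 ± 0.0933 FPKM and 3 of 10 members had no counts. The unnamed gene model Gm42031 had 825 and 67 counts in replicates 1 and 2, a log2 ratio of -3.56, the most negative among differing genes with a mean of at least 5 CPM.

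Of 24 gene lists with at least 5 members at 10 counts, 11 had a median log2 ratio between the 2 libraries outside the middle 95% of random lists, where 1.2 would lie by chance if genes of a list varied independently. Cell cycle genes had a median of 0.09, with 9 of 30 higher in replicate 2 and 0 lower (13 and 0 adjusted over the list alone). NRF2 targets had a median of 0.04, with 13 higher and 6 lower (14 and 7 adjusted over the list alone). Chosen after their values were seen, the higher included Slc7a11 (0.58), Srxn1 (0.48) and Hmox1 (0.19), and the lower Tkt (-0.14) and Gstm1 (-0.12). The unfolded protein and integrated stress response median of 0.004 lay inside random lists. Its members also went both ways, with 6 higher, among them Atf3 (0.50) and Ppp1r15a (0.46), and 4 lower, among them Calr (-0.21). Targets of p53 had a median of 0.08, with 6 higher and 2 lower (7 and 2 adjusted over the list alone), and 2 and 2 with TMM scaling. Fatty acid synthesis genes had a median of -0.12, with 10 lower and 0 higher (11 and 1 adjusted over the list alone). Inflammation and acute phase genes had a median of -0.14, with 4 of 19 lower and 1 higher (7 and 1 adjusted over the list alone). Interferon response genes had a median of -0.17, with 1 of 24 lower and 0 higher (1 and 0 adjusted over the list alone). Fatty acid oxidation genes had a median of -0.05, with 4 of 27 lower and 0 higher (5 and 0 adjusted over the list alone), and 7 and 0 with TMM scaling. Oxidative phosphorylation genes had a median of -0.04, with 6 of 35 lower and 0 higher (7 and 0 adjusted over the list alone). Mesothelial markers had a median of -0.26, with 2 of 5 lower and 0 higher (3 and 0 adjusted over the list alone).

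The higher heat shock genes and lower cholesterol synthesis genes of replicate 2 were weighed against technical sources and a metal response, all tests being chosen after the list medians had been seen and those on scaling and on the metal response also after their own results. The heat shock median of 0.20 came to 0.16 after removal of a trend on GC content (random lists -0.06 to 0.03) and 0.19 after removal of a trend on gene length. The cholesterol synthesis median of -0.18 came to -0.19 and -0.17 in the same order. These values lay outside random lists, which argues against GC content or gene length as the whole cause. TMM scaling gave 0.19 and -0.19, but it moves every gene by the same amount and so decides nothing. A stronger metal response in replicate 2 is a candidate explanation for the heat shock genes, but it cannot be told apart from chance here. The metallothionein and zinc/copper response list had a median of 0.10, inside the -0.11 to 0.14 of random lists, with only 7 members. By the binomial test 2 of these were higher and 0 lower, namely Mt1 and Mt2 at log2 ratios of only 0.06 and 0.08. Differences in culture or handling stay open and untested. Both libraries belong to 1 group, so no difference named by the design could be tested as an explanation.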
